A study of Mus musculus with 8 samples.

How the data were processed

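Whole esophagus RNA from 8 libraries of wild-type mice was used, 5 from untreated water and 3 from water with 0.5% SDS for 14 days, grouped by the treatment given in the labels. Per the labels' protocols, total RNA was extracted with a column kit, selected for poly(A) and made into libraries with the NEBNext Ultra II RNA kit; the same text speaks of cell pellets, while the treatment text and design speak of whole esophagus. The deposited values are raw counts per gene, 1 table per library, with whole numbers for 49315 Ensembl gene identifiers. Per the submitters' processing notes, bcl2fastq, FastQC, STAR 2.6.1c, Subread and the mouse build mm10 were used. The annotation release, the version of Subread, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of paralogs, overlapping genes and antisense genes are therefore uncertain in their division.

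Gene names came from a table of identifiers and symbols that matched 48970 of the identifiers. Coordinates are those of the deposited tables on mm10, and 44858 identifiers had the same start and end in GENCODE M21. Slc7a11 (ENSMUSG00000027737) lies on chromosome 3 from 49892526 to 50443614 on the minus strand, Serpinb3b (ENSMUSG00000073602) on chromosome 1 from 107153940 to 107278361 and Chil1 (ENSMUSG00000064246) on chromosome 1 from 134182176 to 134190181. Sprr2d lies on chromosome 3 from 92339140 to 92340873, S100a9 on chromosome 3 from 90692632 to 90695721, Krt6b on chromosome 15 from 101676034 to 101680289 and Krt16 on chromosome 11 from 100246091 to 100248902. Ache lies on chromosome 5 from 137287519 to 137294466 and Vash2 on chromosome 1 from 190947646 to 190979296. All are protein-coding genes, counted over their exons.

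Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17179, and libraries were scaled by TMM. A quasi-likelihood model with group as its term was fitted with robust estimation (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 29.3%. A standard error is the log2 fold change divided by the square root of F. CPM were taken over TMM-scaled library sizes, and log2 CPM used a prior count of 2. The median log2 fold change of all tested genes was -0.005. No libraries of a group were copies of each other: the lowest chi-square per degree of freedom within a group was 24.2.

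The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The 29 lists were desmosome and cell junction, cornified envelope and squamous differentiation, basal keratinocyte, wound and stress keratinocyte, cell cycle, eosinophil, type 2 cytokines and targets, mast cell, T cell and innate lymphoid cell, B cell and plasma cell, macrophage and dendritic cell, neutrophil, inflammatory cytokine, interferon response, fibroblast and extracellular matrix, skeletal muscle, smooth muscle, adipocyte, endothelium, nerve and Schwann cell, neighbouring organs, red blood cell, cholesterol synthesis, epidermal barrier lipid, NRF2 and xenobiotic, unfolded protein and integrated stress response, epithelial protease and inhibitor, immediate-early response and mitochondrially encoded. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the estimated correlation and fry as alternatives, adjusted over the 28 lists tested. Gene families by symbol stem with at least 8 tested members were tested in the same way.

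Named genes were the 8 largest rises and 8 largest falls among called genes with an established symbol, a mean of at least 5 CPM in a group and group ranges that did not overlap; up to 4 called members of each list, by smallest p; and 22 genes of barrier, type 2 inflammation and proliferation chosen whatever they showed. Capn14 and Clc matched no identifier and were not used here. The count adjusted over the list alone is not reported here for the cholesterol synthesis list. Other genes are named as list members, and those of the closing part were chosen after their values were seen.

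The procedure was tested on simulated counts with 200 genes changed among 16938. Simulated genes varied independently and differences shared by many genes of a library were not simulated, so these rates need not hold for the real libraries. The edgeR test recovered 45% of 2-fold and 83% of 4-fold changes with 9 false calls, DESeq2 1.42.0 recovered 74% and 95% with 57 false calls, and limma-voom 46% and 84% with 11. In 10 simulations without change and with independent genes, list calls appeared in 1.

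Alternatives were size factors by relative log expression, upper quartile scaling, TMM without muscle and the 50 most abundant genes, no filter, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom with and without sample quality weights, glmTreat against a 1.5-fold change, the skeletal muscle list mean as a covariate, the replicate number as a block, and leaving out each library. The adipocyte list mean as a covariate was added after the data were seen. Dixon's ratio was used to look for libraries far from the rest of the 5 controls, and all 56 divisions of the libraries into 3 and 5 were refitted. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.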

Results

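RNA of the whole mouse esophagus was sequenced after 14 days in which the animals drank water with 0.5% sodium dodecyl sulfate (SDS), an anionic detergent of household products, or untreated water. There were 3 SDS libraries and 5 control libraries, prepared from poly(A)-selected RNA. Total counts assigned to genes ranged from 22033866 in control library 2 to 29802362 in control library 3. The SDS libraries held 24682611, 26669024 and 25344951. Mitochondrially encoded genes took between 1.90% and 4.22% of the counts. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these libraries.

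Libraries of the same group were not alike in all respects. The first principal component of the 500 most variable genes held 47.0% of the variance and the next one 33.9%. On the first component SDS libraries 1 and 2 lay at 42.5 and 31.2, and SDS library 3 lay at -7.7, within the range of the controls (-34.3 to 15.8). Control library 4 lay at 40.3 on the other component, the most distant of the controls. Adipocyte markers, which report fat attached to the tissue, differed within the groups: the mean of 11 genes was 3.16 (log2) above the control mean in control library 4 and -3.25 in control library 3. Rank correlations between libraries ran from 0.951 to 0.991 in the controls and from 0.955 to 0.984 in the SDS group.

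**Figure D1:**
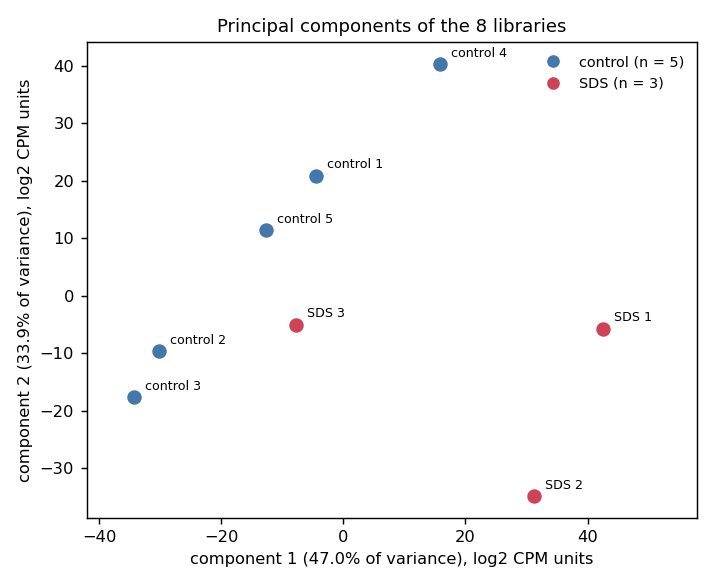
Principal components of the 500 most variable tested genes, with component 1 on the horizontal axis and component 2 on the vertical axis, in log2 CPM units; each point is 1 library, blue for control (n = 5) and red for SDS (n = 3). SDS library 3 lies at -7.7 on component 1, among the controls, and SDS libraries 1 and 2 lie at 42.5 and 31.2.

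The comparison of SDS with control addressed what the detergent does to the epithelium and to inflammation in the esophagus. Slc7a11, the cystine and glutamate exchanger that feeds glutathione synthesis, rose 5.28-fold, from 28.6 ± 3.51 CPM (SD, n = 5) to 151 ± 9.56 CPM (SD, n = 3). Its log2 fold change was 2.40 ± 0.12 (SE), with an adjusted p of 0.00021 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Chil1, a chitinase-like protein of inflamed tissue, rose by 6.97 ± 0.77 (SE) on the log2 scale, and its 3 SDS libraries measured 362, 653 and 71.4 CPM against 1.06 to 5.91 CPM in controls (log2 6.22 without SDS library 2). Calprotectin subunit S100a9 rose by 6.15 ± 0.82 (SE), and the small proline-rich protein Sprr2d by 7.90 ± 0.99 (SE). SDS library 3 lay far below the other SDS libraries: S100a9 measured 3558, 3445 and 173 CPM and Sprr2d 938, 962 and 28.7 CPM in SDS libraries 1, 2 and 3, against at most 46.6 and 3.43 CPM in a control. Over 20 settings their log2 fold changes lay between 5.26 and 6.89 and between 6.81 and 8.47, and each lost its call in 9. Ache, the acetylcholinesterase of the neuromuscular junction, fell by 1.22 on the log2 scale (SE 0.13), from 30.8 ± 3.70 to 13.2 ± 0.929 CPM.

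Of 17179 genes tested, 180 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 107 higher and 73 lower in SDS. By at least 2-fold, 83 were higher and 27 lower. The group ranges did not overlap for 178 of the 180. Among all tested genes they did not overlap for 13.4%, where chance gives 3.57% on average for 3 against 5 libraries. Genes of a library vary together, so a single division can lie far from that average. The share was not computed for the other divisions. The count depended on single libraries: it was 4, 7, 18, 122 and 10 without control library 1, 2, 3, 4 or 5, and 56, 4 and 1222 without SDS library 1, 2 or 3. Higher genes outnumbered lower ones in each of these fits (879 and 343 without SDS library 3) except without SDS library 1 (19 and 37). Of the 31 called genes that the rule for named genes took, Slc7a11 stayed past the threshold in each of these 8 fits, and the other 30 lost their call in 2 to 7 of them, with adjusted p of at most 0.200 and no change of sign.

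**Figure D2:**
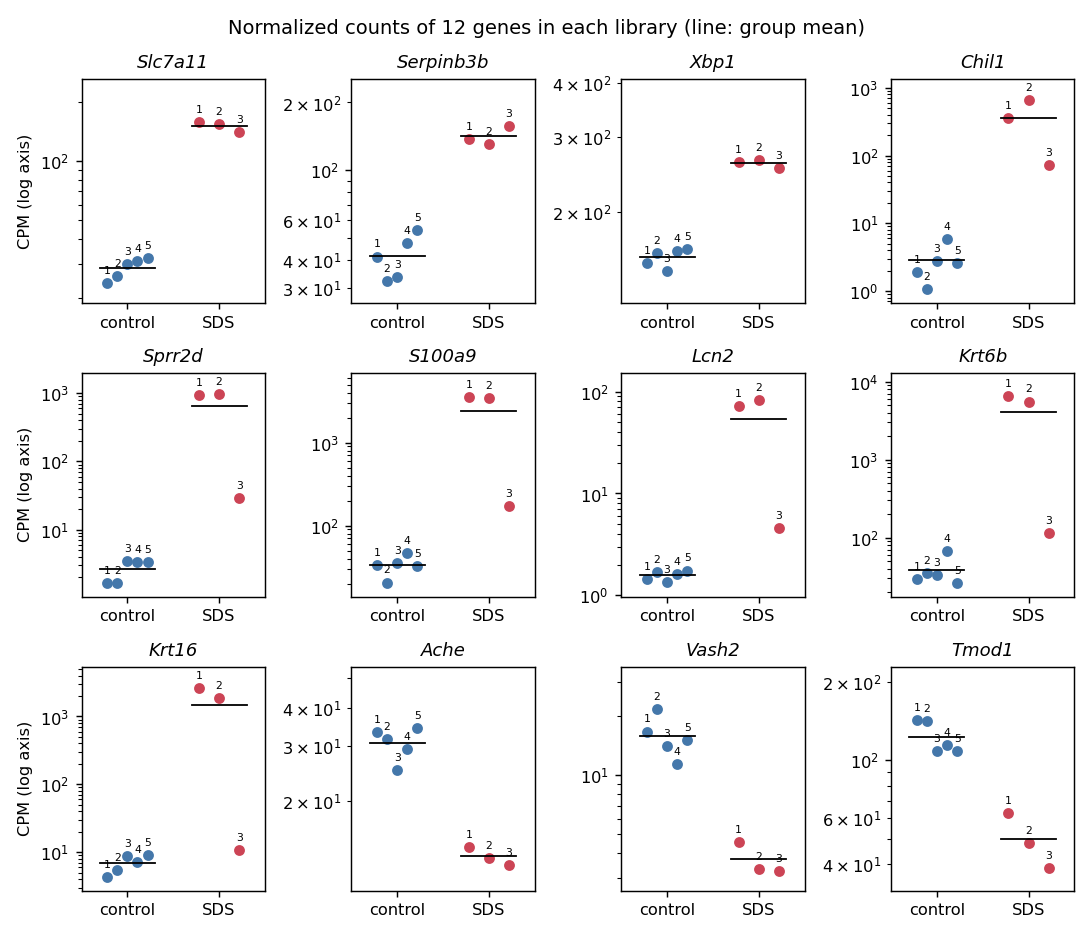
CPM of 12 genes in each library on a logarithmic vertical axis, with control (blue, n = 5) and SDS (red, n = 3) side by side; each point is 1 library with its replicate number and the line is the group mean. Slc7a11 lies at 140 to 159 CPM in the SDS libraries, whereas Krt16 lies at 2608 and 1852 CPM in SDS libraries 1 and 2 and at 10.7 CPM in SDS library 3.

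Part of the keratinocyte genes of wounding and stress rose. Of 24 measured members of the wound and stress keratinocyte list, 6 rose, 0 fell and 18 did not pass over all genes; adjusted over the list alone, 9 rose and 0 fell. The keratins Krt6b and Krt16, which replace the resting keratins in wound edges, rose by 6.74 ± 1.03 and 7.74 ± 1.27 (log2, SE). The beta-defensin Defb3, an antimicrobial peptide, rose by 8.24 ± 1.35, and the siderophore-binding Lcn2 by 5.08 ± 0.73. In SDS libraries 1, 2 and 3 Krt6b measured 6543, 5556 and 115 CPM, Krt16 2608, 1852 and 10.7 CPM, Defb3 85.2, 61.4 and 0.584 CPM and Lcn2 72.3, 82.8 and 4.63 CPM, against at most 66.6, 9.08, 0.332 and 1.75 CPM in a control. Over the settings tried the log2 fold change was 5.45 to 7.90 for Krt6b (call lost in 11 of 20), 5.74 to 8.33 for Krt16 (12 of 20), 7.17 to 9.62 for Defb3 (13 of 19) and 4.29 to 5.97 for Lcn2 (11 of 20). Without SDS library 1 it was 7.06 for Krt16 and 7.58 for Defb3, and without SDS library 3 it was 8.33 for Krt16. The camera test of the list gave an adjusted p of 9.6e-08, and an adjusted p = 0.208 with an estimated correlation. Mean list levels lay 2.73, 2.69 and 0.36 above the control mean in SDS libraries 1, 2 and 3, and the controls spread with an SD of 0.24. Krt6a measured 3567, 2819 and 51.1 CPM in the 3 SDS libraries against 67.0 ± 26.3 CPM in controls, and did not pass (log2 5.00, edgeR quasi-likelihood adjusted p = 0.0538 after Benjamini-Hochberg adjustment); without SDS library 3 it passed (log2 5.58, adjusted p = 2.1e-04).

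In the cornified envelope and squamous differentiation list 4 of 34 measured members rose and 30 did not pass, and adjusted over the list alone the same numbers, 4 and 30, were found. The members that rose were Sprr2d, Sprr2b, Sprr2h and Sprr2a1, small proline-rich proteins that are crosslinked into the cell envelope and are induced in stressed squamous epithelium. Sprr2b rose by 7.72 ± 1.17 and Sprr2a1 by 2.08 ± 0.36 (log2, SE); Sprr2i, which the list does not hold, rose by 7.05 ± 0.93. In SDS libraries 1, 2 and 3 Sprr2b measured 294, 328 and 11.4 CPM, Sprr2i 298, 247 and 10.1 CPM, and Sprr2a1 22.2, 29.6 and 18.5 CPM, against at most 2.13, 2.11 and 8.72 CPM in a control. Over 20 settings the log2 fold change was 7.25 to 9.20 for Sprr2b, 6.07 to 8.02 for Sprr2i and 1.74 to 2.29 for Sprr2a1. Sprr2h measured 94.1, 66.2 and 1.63 CPM in the SDS libraries and rose by 6.44 on the log2 scale (5.77 without SDS library 1). The related Sprr1b (1.40), Sprr1a (-0.20) and Sprr3 (-0.01) did not pass. The list itself did not pass (camera adjusted p = 0.123, and adjusted p = 0.745 with an estimated correlation), with a median of -0.03, a mean of 0.52 and a test direction upward; it passed without control library 2 (0.0448), control library 3 (0.0139) or SDS library 2 (0.0165). Krt13, the abundant suprabasal keratin of the esophagus, stood at 43400 ± 16850 CPM in controls and 52840 ± 16620 CPM in SDS (log2 0.28). Flg, the profilaggrin gene, varied from 7.13 to 317 CPM in controls alone and had a log2 fold change of -1.66 ± 1.31 (SE), which did not pass. Sprr2 genes are close copies of each other, and Sprr2a1 and Sprr2a2 overlap over 5992 bp on the same strand, so reads could be divided among them in counting.

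None of 31 measured members of the desmosome and cell junction list passed over all genes (edgeR quasi-likelihood, with 0 also when adjusted over the list alone), while 3180 of all tested genes had an unadjusted p under 0.05. The list gave a camera adjusted p of 0.123, an adjusted p = 0.764 with an estimated correlation, and a median log2 fold change of 0.16. It passed upward without control library 2 (camera adjusted p = 0.0416), control library 3 (0.00599) or SDS library 2 (0.00786), and downward with the muscle covariate on all 8 libraries (0.0241, median -0.22). Log2 fold changes were 0.42 ± 0.18 for Cldn1, 0.68 ± 0.30 for Dsg1b, 0.33 ± 0.26 for Cdh1, -0.28 ± 0.58 for Dsg1a and -0.03 ± 0.30 for Ocln (SE). Dsg1a, a desmosomal cadherin of the upper epithelium, measured 109, 127 and 475 CPM in the 3 SDS libraries against 101 to 430 CPM in controls. Its fold change turned positive without SDS library 1 (0.07) or SDS library 2 (0.02).

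Among basal keratinocyte genes Krt14 rose by 2.55 ± 0.47 (log2, SE) and measured 5036, 4008 and 1094 CPM in the SDS libraries against at most 822 CPM in a control, and the other 19 of 20 did not pass; adjusted over the list alone 1 rose. Its partner Krt5 measured 2563 ± 882 CPM in controls and 3804 ± 157 CPM in SDS (log2 0.57, not past the threshold). The basal list did not pass (camera adjusted p = 0.108, and adjusted p = 0.745 with an estimated correlation), but passed upward without control library 2 (0.0448), 3 (0.0218) or 5 (0.0301). In the epithelial protease and inhibitor list, Serpinb3b, a squamous serine protease inhibitor, rose 3.39-fold (log2 1.76 ± 0.18), from 41.8 ± 9.35 to 142 ± 13.4 CPM, and the other 28 of 29 did not pass; adjusted over the list alone 7 rose and 0 fell. These 7 included Klk6 at 3.55 ± 0.67, Klk7 at 0.71 ± 0.14 and Serpinb3c at 3.95 ± 0.94 (log2, SE). The list passed upward (camera adjusted p = 2.4e-08, and adjusted p = 0.303 with an estimated correlation), with means 1.06, 0.95 and 0.81 above the control mean in the SDS libraries. Serpinb3b overlaps Serpinb3c over 7161 bp on the same strand and the genes are paralogs, so the division of reads between them is uncertain.

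Of 25 measured members of the cell cycle list 1 rose, the thymidylate synthase Tyms (log2 0.80 ± 0.13, from 5.58 to 9.68 CPM), and 24 did not pass over all genes; adjusted over the list alone, 23 rose and 1 fell, the latter Ube2c. The list passed upward (camera adjusted p = 6.0e-16, and adjusted p = 0.208 with an estimated correlation), with means of 0.80, 1.42 and 0.39 above the control mean in the SDS libraries, a control SD of 0.29 and 0.36 in control library 2, the highest control. The proliferation marker Mki67 measured 45.6, 94.3 and 41.5 CPM against 24.4 ± 5.20 CPM in controls and did not pass (log2 1.31, edgeR quasi-likelihood adjusted p = 0.0678 after Benjamini-Hochberg adjustment). Without SDS library 3 it passed, with a log2 fold change of 1.53 and an adjusted p of 0.0239.

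Among stress response genes, Xbp1, a transcription factor of the unfolded protein response, rose 1.65-fold, from 157 ± 7.99 to 260 ± 5.25 CPM, and 19 of the 20 list members did not pass; adjusted over the list alone 8 rose and 1 fell, Chac1. The unfolded protein and integrated stress response list passed upward (camera adjusted p = 0.00130, and adjusted p = 0.208 with an estimated correlation), and its means were 0.25, 0.21 and 0.16 above the control mean. In the NRF2 and xenobiotic list, a set of glutathione and detoxification genes, Slc7a11 rose and 23 of 24 did not pass; adjusted over the list alone 2 rose, with Akr1b8 at 1.09 ± 0.25 (log2, SE). That list did not pass (camera adjusted p = 0.163, and adjusted p = 0.745 with an estimated correlation), and its median of -0.08 lay opposite to the upward test direction; it passed upward without SDS library 2 (0.0128). The serine palmitoyltransferase subunit Sptlc1, which starts sphingolipid synthesis, rose 1.74-fold, 1 of 26 in the epidermal barrier lipid list; adjusted over the list alone 2 rose and 1 fell, Sptlc2 at 0.62 and Cers4 at -0.64. The barrier lipid list did not pass (camera adjusted p = 0.123, and adjusted p = 0.745 with an estimated correlation), but passed upward without control library 3 (0.0168), SDS library 1 (0.0476) or SDS library 2 (0.00786).

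The neutrophil, T cell and innate lymphoid cell, and macrophage and dendritic cell lists moved mainly in SDS libraries 1 and 2. Of 9 measured neutrophil genes 2 rose, S100a9 and S100a8 (2533, 2304 and 24.7 CPM in the SDS libraries), which keratinocytes also express, and 7 did not pass. Adjusted over the list alone 4 rose and 1 fell. S100a8, S100a9 and Mmp9 are also members of the wound and stress keratinocyte list, so the results of these lists are not separate. The receptor Csf3r measured 22.8, 45.4 and 0.542 CPM in the 3 SDS libraries against a control mean of 0.592 CPM. The neutrophil list passed upward (camera adjusted p = 0.00034, and adjusted p = 0.208 with an estimated correlation), with means 3.48, 3.60 and 0.35 above the control mean. In the T cell and innate lymphoid cell list Cd3d rose by 4.04 ± 0.75 (log2, SE; 5.04 without control library 4) from a mean of 0.0760 CPM, and 16 of 17 did not pass; adjusted over the list alone 11 rose and 0 fell, among them Il7r at 2.38 and Zap70 at 3.38. It passed upward (camera adjusted p = 2.2e-09, and adjusted p = 0.208 with an estimated correlation), with means of 2.18, 2.27 and 0.26. In the macrophage and dendritic cell list Cd207, the langerin of Langerhans cells, rose by 3.59 ± 0.45 and measured 10.4, 5.94 and 4.13 CPM against 0.558 ± 0.287 CPM in controls. The other 24 of 25 did not pass; adjusted over the list alone 15 rose and 0 fell, and the list passed upward (camera adjusted p = 4.9e-12, and adjusted p = 0.416 with an estimated correlation), with means of 1.34, 2.22 and -0.07.

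The B cell and plasma cell list was highest in SDS library 3. Cd22 rose by 3.80 ± 0.58 (log2, SE) from 9 counts over the 5 controls to 77 counts over the 3 SDS libraries, and 10 of 11 members did not pass; adjusted over the list alone 3 rose and 0 fell, with Cd79b at 2.08 and Cd79a at 2.33. The list passed upward (camera adjusted p = 4.7e-06, and adjusted p = 0.208 with an estimated correlation), with means of 0.83, 1.40 and 1.57 in SDS libraries 1, 2 and 3. Mast cell genes did not pass: 0 of 9 over all genes and 0 of 9 adjusted over the list alone, by the edgeR quasi-likelihood test. The mast cell list had a median of -0.32 against an upward test direction (camera adjusted p = 0.500, and adjusted p = 0.850 with an estimated correlation), and control library 4 stood 2.18 above the control mean.

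Most eosinophil markers had too few counts for the filter. Of 11 matched eosinophil markers 2 passed it, Ear2 (log2 -0.00 ± 0.52, 1.57 CPM in controls) and Alox15 (-0.16 ± 1.31, 13.0 CPM in controls), and neither was called. The granule protein genes Prg2 and Epx had 5 and 4 counts over the 5 controls and 3 and 0 counts over the 3 SDS libraries. Siglecf, a surface lectin of eosinophils and some macrophages, had 28, 41 and 0 counts in the 3 SDS libraries and 1 to 5 in each control, too few for the filter. Without a filter Siglecf (edgeR quasi-likelihood adjusted p = 0.157), Prg2 (0.981) and Epx (0.555) did not pass. At these library sizes 3 counts correspond to 0.101 to 0.136 CPM, so a fall or a small rise of these granule genes was not detectable at this depth. That floor covers counting error only.

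Type 2 cytokine genes gave 1 call over all genes. Il13ra1, a subunit of the interleukin 13 receptor, rose 2.24-fold, from 28.2 ± 4.72 to 63.0 ± 16.3 CPM, and 21 of 22 measured members did not pass. Adjusted over the list alone 4 rose (Il13ra1, Ccl8, Ccl22 and Il4ra) and 2 fell (Il5 and Cish). The list did not pass (camera adjusted p = 0.123, and adjusted p = 0.745 with an estimated correlation), but passed upward without SDS library 3 (0.00697). Il5 measured 0.629, 0.668 and 0.709 CPM in SDS against 1.49 ± 0.186 CPM in controls, with a log2 fold change of -1.15 (edgeR quasi-likelihood adjusted p = 0.0538 after Benjamini-Hochberg adjustment, and -1.19 with 0.0391 without SDS library 3). Il13 had 0 counts in each of the 8 libraries. The eosinophil chemokines Ccl11 and Ccl24 had log2 fold changes of -0.24 ± 0.36 and -0.55 ± 0.25, and the epithelial cytokines Il33 and Tslp of 0.22 ± 0.29 and -0.12 ± 0.38 (SE); none of these passed. The fold change of Tslp was 0.09 without control library 1 and 0.19 without SDS library 3. Spink7, an esophageal protease inhibitor, had 9 counts over the controls and 0 over the SDS libraries, too few for the filter, and did not pass without one (edgeR quasi-likelihood adjusted p = 0.441).

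Inflammatory cytokine and interferon genes gave few calls. In the inflammatory cytokine list 0 of 14 passed over all genes and 1 rose adjusted over the list alone, Il1b, which measured 10.7, 12.7 and 0.876 CPM in SDS against 0.933 ± 0.500 CPM in controls. Il1b had a log2 fold change of 3.11 (edgeR quasi-likelihood adjusted p = 0.0769 after Benjamini-Hochberg adjustment, and 3.64 with 0.00319 without SDS library 3). Il17f, which had too few counts for the filter, passed without one (edgeR quasi-likelihood adjusted p = 0.0392). It lost that call in 7 of the 8 fits without 1 library (adjusted p up to 0.166). The cytokine list did not pass (camera adjusted p = 0.362, and adjusted p = 0.745 with an estimated correlation), but passed upward without SDS library 3 (8.3e-06). The interferon response list passed upward with a median of 0.46 (camera adjusted p = 0.0184, and adjusted p = 0.745 with an estimated correlation), with 0 of 27 members past the threshold over all genes or adjusted over the list alone in the edgeR quasi-likelihood test. Its means were 0.32, 1.12 and -0.19 in the SDS libraries, and control library 4 stood at 0.71; the interferon call was lost without control library 3 (0.0796) or SDS library 2 (0.708).

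Genes of striated muscle, which forms the muscle coat of the mouse esophagus, were lower. None of the 24 skeletal muscle list members passed over all genes in the edgeR quasi-likelihood test, although each had a negative fold change; adjusted over the list alone 18 fell and 0 rose. The muscle creatine kinase Ckm measured 2564 CPM in SDS against 4787 CPM in controls (log2 -0.90 ± 0.23), titin (Ttn) had -0.88 ± 0.21 and Eno3 -1.01 ± 0.20 (SE). The list passed downward (camera adjusted p = 6.0e-16, and adjusted p = 0.208 with an estimated correlation), with means of -0.37, -0.95 and -1.21 in the SDS libraries and -0.30 to 0.39 in the controls. Outside the list, Tmod1, a cap of thin filaments, fell by 1.30 on the log2 scale, the Z-disc protein gene Myoz3 by 1.23, Wnk2 by 1.28 and Katnal2 by 1.30. Vash2, a tubulin carboxypeptidase gene, fell by 2.08 (SE 0.24), from 15.8 ± 3.81 to 3.72 ± 0.730 CPM. Tmem233 and Atcay fell by 1.36 and 1.66, and Atcay overlaps the antisense gene Atcayos over 6370 bp, so without strand information their reads could not be told apart.

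Smooth muscle and nerve lists passed downward in the edgeR fit with all 8 libraries and no covariate. The smooth muscle list had 0 of 12 members past the threshold over all genes and 0 adjusted over the list alone in the edgeR quasi-likelihood test, a median of -0.71 and a camera adjusted p of 0.00356, with an adjusted p = 0.745 with an estimated correlation. Its means were 0.21, -0.99 and -0.99 in the SDS libraries, and the controls ran from -0.91 to 1.35. The smooth muscle call was lost without control library 4 (0.0725) or SDS library 3 (0.0603), with voom quality weights (0.477), where the median was 0.21, and with the muscle covariate (0.624), where the median was 0.23 and the test direction turned upward. In the nerve and Schwann cell list 0 of 14 passed over all genes; adjusted over the list alone 1 fell, the neuronal nitric oxide synthase Nos1 (log2 -1.48 ± 0.31, from 148 to 53.1 CPM), and the camera test gave an adjusted p of 0.0150 and an adjusted p = 0.691 with an estimated correlation. The nerve call was lost without SDS library 3 (0.0740), with voom quality weights (0.0626) and with the muscle covariate (0.646). The mitochondrially encoded list had 0 of 13 members past the threshold in either way, a median of -0.38, a camera adjusted p of 0.0150 and an adjusted p = 0.745 with an estimated correlation. Its call was lost without control library 4 (0.0729) or SDS library 2 (0.255), with voom quality weights (0.308) and with the muscle covariate (0.441), where it turned upward.

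Of the remaining lists, cholesterol synthesis passed upward with a median of 0.34 (camera adjusted p = 0.00356, and adjusted p = 0.745 with an estimated correlation), and 0 of 24 members passed over all genes in the edgeR quasi-likelihood test. The cholesterol call was lost without SDS library 3 (0.624), with voom quality weights (0.300) and with the muscle covariate (0.0652), where it turned downward. Without SDS library 3 the fibroblast (2.4e-05) and endothelium (0.0117) lists passed upward, and without SDS library 2 the fibroblast list passed downward (0.00467). The fibroblast and extracellular matrix list did not pass (camera adjusted p = 0.469, and adjusted p = 0.854 with an estimated correlation), with means of 0.45, 1.27 and -1.27 in the SDS libraries; adjusted over the list alone 1 of 26 rose, Timp1. Endothelium did not pass (camera adjusted p = 0.210, and adjusted p = 0.764 with an estimated correlation), and Selp was the 1 of 16 that rose adjusted over the list alone. Immediate-early genes did not pass (camera adjusted p = 0.111, and adjusted p = 0.745 with an estimated correlation); adjusted over the list alone 2 of 17 fell, Nr4a1 at -1.60 and Jun at -0.68, and the list passed downward without control library 1 (0.00576), 2 (0.0413) or 4 (0.0368). Adipocyte (11 genes, camera adjusted p = 0.123), red blood cell (5 genes, 0.287) and neighbouring organ (3 genes, 0.722) lists did not pass and had 0 members past the threshold over all genes or adjusted over the list alone; with an estimated correlation their adjusted p were 0.745, 0.745 and 0.850. The adipocyte list passed downward without control library 2 (0.0413), control library 3 (0.0117) or SDS library 1 (0.00434), and the red blood cell list upward without control library 4 (0.0291) or SDS library 2 (0.00786).

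In total 14 of the 28 lists tested passed with the preset correlation, 10 upward and 4 downward. With an estimated correlation none passed (6 had an unadjusted p under 0.05), and with fry 2 passed, B cell and plasma cell (adjusted p = 0.0427) and unfolded protein and integrated stress response (adjusted p = 0.0397). At least 14 lists passed in 37 of the 56 ways of dividing the 8 libraries into 3 and 5.

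**Figure D3:**
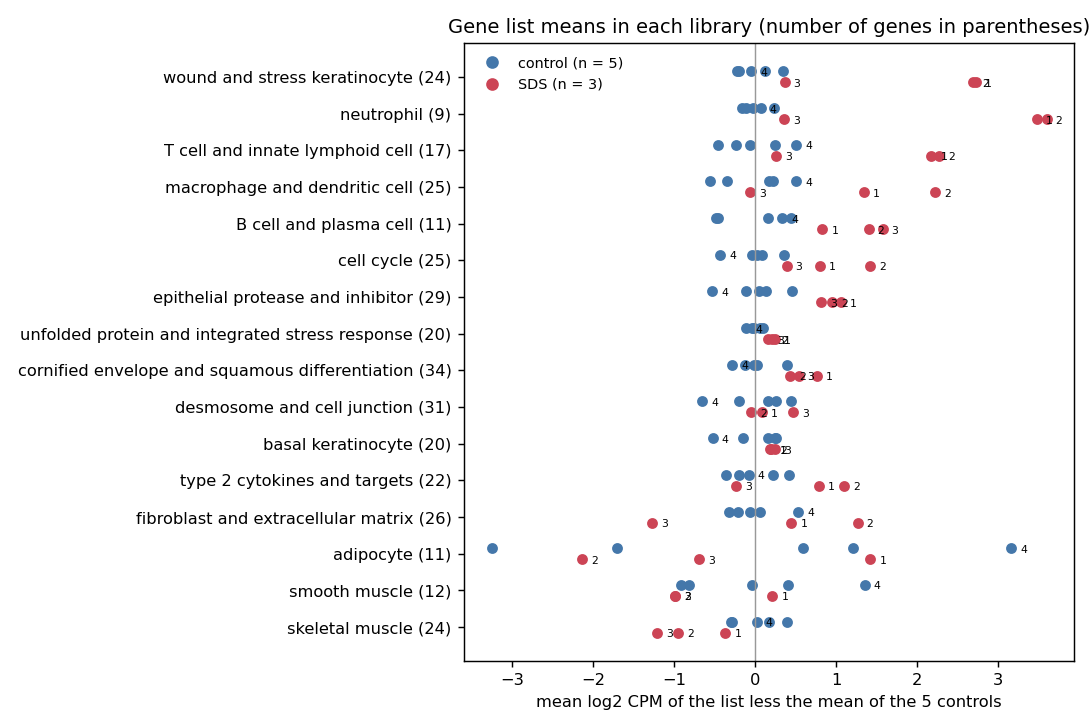
Mean log2 CPM of each gene list in each library less the mean of the 5 controls (horizontal axis), for 16 lists (vertical axis, with the number of genes in parentheses); each point is 1 library, blue for control and red for SDS, and numbers mark the SDS libraries and control library 4. The wound and stress keratinocyte mean lies at 2.73 and 2.69 in SDS libraries 1 and 2 and at 0.36 in SDS library 3, whereas the skeletal muscle mean lies below 0 in all 3 SDS libraries.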

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

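The tests of a wrong label, of exchanged labels, of the amount of subepithelial tissue and of the scaling were chosen only after the result was seen; the counts over other divisions of the libraries and the test of the muscle share were planned.

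Control library 4 lay far from the other 4 controls in 2 of the 80 sets of control values examined, where chance gives about 4. Krt6b measured 66.6 CPM there and 26.3 to 34.9 CPM in the other controls. Cd3d measured 0.237 CPM there and 0 to 0.0683 CPM in the others, which is a matter of few counts. The SDS group of 3 was not examined in this way.

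At least as many genes as the 180 of the real division appeared in 2 of the 56 divisions into 3 and 5, the real one included. As the other of these mixed the groups and called more genes, this rank cannot settle whether chance accounts for the gene count. The highest other division gave 581 genes, joining control library 4 with SDS libraries 1 and 2, and 15 of these were among the 180; that points to a structure of the samples. For the gene lists, 37 of the 56 divisions gave at least the 14 of the real one, with 21 as the highest other, so chance cannot be excluded. For the gene families, 18 of 56 gave at least 19, with 28 as the highest other, and chance cannot be excluded there.

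Over genes called without it, SDS library 3 lay near the controls on a scale from the control mean (0) to the mean of SDS libraries 1 and 2 (1): it lay above the left-out control in 4 of 5 fits (0.191, 0.184, 0.224 and 0.216 against 0.035, -0.062, 0.018 and 0.058) and below it where control library 4 was left out (0.161 against 0.287). Those 4 fits go against a wrong label, as do its 8 day-phase clock genes outside the called ones, at -0.324 against the lowest control at -0.138. Its mean position of 0.195, however, lies within the range of the left-out controls. A wrong label can therefore not be told apart from a response that was weak in the median gene. The clock condition was added after the first outcome, which alone would have met the explanation. The response was not weak in every gene: Slc7a11, Serpinb3b and Xbp1 measured 140, 157 and 254 CPM in SDS library 3. Controls measured at most 32.2, 54.4 and 165 CPM. These genes were picked from calls that used SDS library 3 as an SDS library, so they cannot settle its label. An exchange with control library 4 also stays open, with values on both sides. Over 1969 genes called without either, control library 4 lay at 0.287, above SDS library 3 at 0.161 and the next control at 0.058, yet below 0.5. The division that joined control library 4 with SDS libraries 1 and 2 called 581 genes. Against an exchange, Slc7a11 measured 140 CPM in SDS library 3 and 31.0 CPM in control library 4. The skeletal muscle list mean lay at -1.21 in SDS library 3 and at 0.02 in control library 4. The day-phase clock genes outside the called ones lay at -0.324 and 0.150. A smaller share of subepithelial tissue in the piece of SDS library 3 is argued against for the wound list. The wound mean less the basal keratinocyte mean was 0.112 there and 2.49 or more in SDS libraries 1 and 2 (control SD 0.312). Both are keratinocyte lists, which such a smaller share would hardly lower, so this comparison tested little. For the T cell list a smaller share of subepithelial tissue stays open. The T cell mean less the fibroblast mean was 1.53 in SDS library 3 and 1.01 in the lower of the others. That value rests on the fibroblast list, at -1.27 there and 0.45 and 1.27 in SDS libraries 1 and 2. The endothelium list fell less (-0.33 there, 0.60 and 0.49 in the others), and the B cell and plasma cell list was highest there (1.57). A difference in how much each animal drank or responded was not tested.

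The 73 lower genes accompanied a fall of the skeletal muscle list by 0.84 on the log2 scale. The lower genes fell further than their slope on the muscle list in the controls predicts, by a median of -0.64 (log2, and -0.70 to -0.59 without 1 control). This cannot decide whether a lower share of striated muscle RNA is the whole cause, as the genes were chosen for their fall in these libraries. The slopes were also carried beyond the controls, whose muscle means ran from -0.30 to 0.39, to -0.37, -0.95 and -1.21 in the SDS libraries. With the muscle list as a covariate the median of the lower genes went from -0.94 (SE 0.15) to -0.63 (SE 0.19). All 73 stayed negative, and none kept its call, with the smaller median change and the larger error given here. Scaling by abundant muscle transcripts is argued against, as 70 of the 73 stayed past the threshold when these were left out of the scaling. A change of muscle or nerve by the treatment, or a lower muscle share as a part or the whole of the cause, stays open.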

How the results depend on the processing

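The adipocyte covariate and the settings of the family scan and of the sample distances were chosen after the data were seen; the other alternatives were planned. The 180 genes became 1610 with DESeq2 and 1948 with voom quality weights, 403 with the adipocyte covariate, 9 with glmTreat and 2 with the muscle covariate (1422 at an unadjusted p under 0.05). With 1 library left out they ranged from 4 to 1222 (4, 7, 18, 122 and 10 without control library 1, 2, 3, 4 and 5; 56, 4 and 1222 without SDS library 1, 2 and 3). The 14 lists became 0 with the estimated correlation and 2 with fry, and ranged from 14 to 19 with 1 library left out; 12 lists passed with voom quality weights, 11 upward and 1 downward, and 4 of the 14 lost their call. The 19 families became 0 with the estimated correlation and 32 without a filter, and ranged from 17 to 23. The share of the first component, 47.0%, ranged from 43.3% to 60.4%. The cause of these changes was not tested. The replicate block, which only 6 libraries inform, called 0 genes in edgeR (3173 at an unadjusted p under 0.05) and 17 lists, with the calls of smooth muscle (median 0.075, camera adjusted p = 0.264) and nerve (-0.127, 0.136) lost. Deviations of same-numbered libraries correlated at 0.311, -0.006 and 0.307. SDS library 1 correlated best with control library 4 (0.509), and SDS library 2 with no control by more than 0.023. The numbers were therefore not taken to pair animals. Of the 31 called named genes none changed sign under any setting. Slc7a11 kept its call in 19 of 20 settings (log2 2.27 to 2.51; adjusted p = 0.0615 in edgeR with the block).

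Changes of direction were found in genes and lists as follows, and their cause was not tested; values are log2 fold changes or, for a list whose camera direction turned, its median. Without a filter, neighbouring organs gave -0.12. With DESeq2, mast cell gave -0.32. With voom quality weights, Krt13 gave -0.004, Ccl11 0.13, Tslp 0.18, desmosome 0.028, cornified envelope -0.18, adipocyte 0.65 and NRF2 -0.24. With the muscle covariate, Dsg1b gave -0.055, Cdh1 -0.12, Il33 -0.32, Krt13 -0.40, Ccl11 0.75, Tslp 1.03, desmosome -0.22 (where it passed downward), cornified envelope -0.43, basal -0.10, smooth muscle 0.23, adipocyte 0.51, neighbouring organs 0.60, cholesterol -0.23, barrier lipid -0.20, NRF2 -0.47 and mitochondrial 0.034. With the adipocyte covariate, adipocyte gave 0.16. With the replicate block, desmosome gave 0.042, adipocyte 0.80 and NRF2 -0.25. With 1 library left out, Dsg1a ranged from -1.28 to 0.066 (above 0 without SDS library 1 or 2), Tslp from -0.41 to 0.19 (above 0 without control library 1 or SDS library 3), Ocln from -0.39 to 0.16 (above 0 without control library 2 or 3 or SDS library 1 or 2) and mast cell from -0.75 to 0.51 (test direction turned without control library 3 or SDS library 1). Fibroblast ranged from -0.38 without SDS library 2, where it passed downward, to 0.68 without SDS library 3. Neighbouring organs ranged from -0.88 to -0.055 (turned without control library 4), and without SDS library 3 the test direction turned in desmosome (0.028 to 0.30), red blood cell (-0.21 to 1.03), barrier lipid (-0.019 to 0.24) and NRF2 (-0.27 to 0.11).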

Other observations

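The clock tests and the fits without 1 library were chosen only after the result was seen, as were the genes named in this part; the family scan was planned.

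Several leukocyte and cytokine genes had too few counts for the filter and were tested only without one, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Il17a and Il17f, cytokines of T cells and innate lymphoid cells that act on epithelium, had 61 and 57 counts in SDS library 1, 55 and 43 in SDS library 2, 0 and 1 in SDS library 3 and at most 1 in any control. Trem1, an activating receptor of neutrophils and monocytes, had 40, 68 and 3 counts in the SDS libraries and at most 1 in a control. The neutrophil chemokine Cxcl5 had 57, 168 and 0 counts against 0 to 5 in the controls. Ccr3, the receptor of the eotaxins, had 15, 16 and 4 counts against 0 to 6. Without the filter Trem1 (adjusted p = 0.0279) and Il17f (0.0392) passed upward, as did the formyl peptide receptor genes Fpr1 (0.0407) and Fpr2 (0.0307), and Il17a (0.0589), Cxcl5 (0.178) and Ccr3 (0.142) did not. The other neutrophil list members below the filter, Mmp8, Mpo, Elane, Ly6g, Retnlg, Ngp and Stfa2l1, did not pass either (edgeR quasi-likelihood adjusted p from 0.0566 to 0.811). Ly6g had 1, 3 and 0 counts in the SDS libraries. Of the 8 unfiltered fits without 1 library, the call was lost in 6 for Trem1 and Fpr2 (adjusted p up to 0.112 and 0.199) and in 7 for Il17f and Fpr1 (up to 0.166 and 0.284): all 4 kept it without SDS library 3, and Trem1 and Fpr2 also without control library 4. Without SDS library 3 Il17a (3.6e-05), Cxcl5 (0.00500) and Ccr3 (0.0492) passed. Rnase2b, of the family of eosinophil-associated ribonucleases, rose by 4.21 ± 0.45 (log2, SE) from 6.95 to 129 CPM and measured 189, 161 and 35.8 CPM in the SDS libraries (edgeR quasi-likelihood adjusted p = 0.0118 after Benjamini-Hochberg adjustment). Its call was lost without control library 1 (0.0673), 2 (0.0553) or 5 (0.0595) or SDS library 2 (0.0681), with log2 fold changes of 3.82 to 4.66 over the 8 fits without 1 library. Its relatives Rnase2a and Ear2 had log2 fold changes of -0.82 and -0.00 and did not pass, and reads of such copies can be divided in counting.

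Of 274 gene families by symbol stem, 19 passed the camera test, and none did with an estimated correlation (11 had an unadjusted p under 0.05). The Sprr family led, with 9 of 14 members rising and a median log2 fold change of 2.78 (camera adjusted p = 1.3e-16, and adjusted p = 0.986 with an estimated correlation). The family with the symbol stem Rpl, which was not limited to protein-coding genes, had a median of 0.28 over 76 members. Of these 0 passed the threshold in the edgeR quasi-likelihood test (camera adjusted p = 8.1e-05, and adjusted p = 0.986 with an estimated correlation).

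Nr1d1, Dbp and Cry2, repressors and output genes of the circadian clock, fell by 1.02, 0.97 and 0.80 on the log2 scale (edgeR quasi-likelihood adjusted p = 0.0303, 0.0321 and 0.0309 after Benjamini-Hochberg adjustment). Nr1d1 and Dbp lost their call without control library 1 (0.0955 for both), 2 (0.0854 and 0.0892), 3 (0.0606 and 0.0590) or 5 (0.0978 and 0.0976) and without SDS library 1 (0.0685 and 0.0619) or 2 (0.147 and 0.170), and Cry2 without control library 1 (0.0955), 2 (0.0867), 3 (0.0683) or 5 (0.0978) or SDS library 2 (0.156), with no change of sign. Of the 16 clock genes examined only these 3 passed. Over 11 day-phase genes the mean difference was -0.59, lower in 3 of 3 SDS libraries than in any control. Per1 and Per2 moved least among them (-0.24 and -0.15). Over 5 genes of the opposite phase it was 0.34 (exact permutation p = 0.0536). Nfil3 had the largest rise there (0.86), with 1.35, 1.14 and -0.26 in SDS libraries 1, 2 and 3, and Cry1 went the other way (-0.21). The difference between the phases was -0.93 (exact permutation p = 0.0179, the smallest that 56 divisions can give). Since the 3 called genes prompted the test, it was repeated on the other 13, in the same 8 libraries and so not independently of those calls. The repeat gave a difference of -0.80 with the same exact permutation p of 0.0179. This is consistent with collection at a different time of day, which the labels do not give, but the opposite phase alone did not pass, and an effect of SDS on the clock, or on feeding and drinking times, was not tested.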
